A study of Mus musculus with 12 samples.

How the data were processed

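RNA was measured in 12 libraries of regulatory T cells (Tregs) from the mouse omentum, a fat tissue of the abdominal cavity that holds immune cells. Per the labels, the mice were female and were housed under specific pathogen-free (SPF) or germ-free (GF) conditions. Tumor-free mice were taken at day 0 and tumor-bearing mice at day 15 after intraperitoneal injection of EG7.1.15 tumor cells at 8 to 12 weeks of age, per the labels' protocols. The age of the tumor-free mice is not given in the sources used here. Cells were sorted as live CD45.2+ CD4+ CD25+ cells with GFP reported from Foxp3, the transcription factor that defines Tregs, per the labels' protocols. RNA was isolated with a Quick-RNA MicroPrep kit, amplified with the SMART-seq v4 kit, which copies full-length transcripts from few cells, and made into libraries from 200 pg of cDNA with Nextera XT, per the labels' protocols. No molecular identifiers are mentioned in the sources used here, so reads were not taken as independent molecules. The printed SEs and limits come from the model below and cover the variation between libraries.

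Reads were trimmed with Trim Galore 0.44, aligned to mm10 with TopHat2 2.1.1, handled with SAMtools 1.9 and counted per gene with HTSeq 0.6.1, per the submitters' processing notes. The same notes name DESeq2 1.20.0 for the study's own normalization and testing. The values used here are the deposited raw counts of reads per gene, as whole numbers, together with the 5 totals that HTSeq writes for reads given to no gene. The annotation and the strand setting used for counting are not given in the sources used here, so reads of overlapping or antisense genes could not be told apart. Reads aligned to more than 1 place were left out of the counts by HTSeq's own category, which lowers genes with close copies or pseudogenes. Levels are therefore uncertain for ribosomal protein genes, for Hspa1a and Hspa1b, for Ifit3, for Atp5b and for the glycolytic genes Tpi1, Pgk1, Pgam1 and Gapdh.

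The files held 24421 gene rows and 5 rows naming no gene, which were removed. The library sizes ran from 1.72 M to 13.5 M reads (M, mega) assigned to genes, and 18909 to 22032 genes had at least 1 read. Gene symbols were used as the files give them, and 16943 of the 17604 tested symbols matched an entry of GENCODE M21 on GRCm38 (mm10), from which coordinates were taken. All coordinates are counted from 1.

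The main test was the edgeR quasi-likelihood F test (edgeR 4.0.16 in R 4.3.3) on 1 model with a mean for each of the 4 groups, which leaves 8 residual degrees of freedom. Genes were kept by filterByExpr with a minimum count of 10 and a minimum total of 15, libraries were scaled by TMM, and p-values were adjusted over all 17604 tested genes by the Benjamini-Hochberg method with a threshold of 0.05. The common dispersion was 0.169. Levels are printed as TMM-scaled counts per M reads (CPM), computed here, as mean ± SD over 3 libraries. Fold changes are log2 values ± SE from the model. The 6 contrasts were GF against SPF in tumor-free mice, GF against SPF in tumor-bearing mice, tumor-bearing against tumor-free in SPF mice, the same in GF mice, the interaction of housing and tumor, and GF against SPF averaged over both tumor states. The groups, tests, lists and the first set of other settings were fixed before the data were examined.

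The rule for named genes was fixed for the first 5 contrasts. It takes Foxp3, Il2ra, Cd4 and Ptprc always. It takes up to 10 higher and up to 10 lower genes with the smallest p among those that passed and whose groups did not overlap (no overlap condition for the interaction), without predicted or unnamed genes and receptor segments. For each list it takes up to 4 passing members, or else up to 2 members with the smallest p as values only. Where fewer than 10 genes passed, it takes all of them and the next 5 as values only, and for the interaction it adds the fold changes in each housing. The rule was extended to the averaged contrast after the data were seen, without the 4 genes of the sort, and the text names a selection of the genes that the rule takes. A gene among those it takes is not reported here.

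A total of 36 gene lists were fixed from textbook knowledge. They covered Treg identity, Treg suppressive molecules, adipose and tissue Tregs, resting T cells, type 17, type 1 and type 2 programs, both interferon responses, cell cycle, mTORC1 target genes, glycolysis, oxidative phosphorylation, cholesterol synthesis, arginine and polyamine metabolism, integrated stress response, immediate early genes, NF-kB target genes, chemokine and homing receptors, class I antigen presentation, ribosomal proteins and mitochondrially encoded genes. A further set of 14 of the 36 lists held markers of other cells: CD8 and cytotoxic T cells, conventional CD4 T cells, NK cells, B cells, plasma cells, macrophages and monocytes, dendritic cells, neutrophils and mast cells, mesothelial cells, adipocytes, fibroblasts, endothelial cells, erythroid cells and immature thymocytes. Lists with at least 5 tested genes, 34 in all, were tested with camera (limma 3.58.1) at a preset correlation of 0.01, and again with an estimated correlation and with fry. The preset test treats genes of a list as nearly independent, and the estimated correlation allows for genes that vary together between libraries. List p-values were adjusted over the 34 lists of a contrast. The mitochondrially encoded list had 0 members in the files, and the erythroid list had 1 tested gene, Alas2.

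The first set of other settings held DESeq2 size factors, no filter, a stricter filter (a CPM of at least 5 in 3 libraries), the replicate number as a block and counts thinned to the smallest library. It also held the DESeq2 1.42.0 Wald test, limma-voom with quality weights, a model of only the 2 groups compared, and each library left out in turn. A further set of 3 settings was chosen after seeing the data: the share of reads assigned to genes as a covariate, an other-cell marker score as a covariate, and leaving out the SPF library with the lowest assigned share in both tumor states. The 16 pan-T genes, which T cells of any kind express (such as Cd3e, Cd2 and Lck), were also chosen after seeing the data. The score was the mean log2 CPM over the B cell, plasma cell, macrophage, dendritic cell and fibroblast lists.

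The procedure was tested on simulated counts with a share of genes changed 2-fold, 4-fold or 8-fold, drawn from the real means and library sizes. For tumor-free GF against SPF, edgeR recovered 10.4% of the 2-fold, 65.7% of the 4-fold and 81.8% of the 8-fold changes, with 4 false calls among the 17091 genes the test ran on. For tumor-bearing GF against SPF the shares were 1.49%, 64.2% and 84.8%. For the tumor contrast they were 11.9%, 52.2% and 90.9% in SPF mice and 4.48%, 56.7% and 90.9% in GF mice. They were 1.49%, 25.4% and 59.1% for the interaction and 34.3%, 89.6% and 100% for the averaged contrast. Over the 6 contrasts edgeR made 2 to 6 false calls and DESeq2 made 22 to 46. Each gene was drawn independently, and the changed genes were taken from the more abundant ones. Differences between libraries that many genes share were not simulated, so these rates may not hold for the real libraries. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.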

Results

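Transcripts of omental Tregs were counted in 12 libraries from 4 groups of mice, with 3 libraries in each group: SPF tumor-free, SPF tumor-bearing, GF tumor-free and GF tumor-bearing. The purpose stated with the series is the effect of the microbiota on the transcriptome of these cells. The SPF tumor-free libraries 1, 2 and 3 held 4.56 M, 13.2 M and 1.72 M reads (M, mega) assigned to genes. The SPF tumor-bearing libraries, which are numbered 2, 3 and 4, held 4.67 M, 9.89 M and 7.91 M. The GF tumor-free libraries held 6.03 M, 5.1 M and 5.01 M, and the GF tumor-bearing libraries held 8.56 M, 13.5 M and 10.99 M. The 10 most abundant genes took 6.00% to 8.25% of the gene reads.

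The genes that define the sort were abundant in each library. Foxp3, which encodes the transcription factor that specifies Tregs (chromosome X, 7573644 to 7595245, GRCm38), was present at 485 to 1993 CPM. Il2ra, which encodes CD25, was present at 292 to 1936 CPM and Cd4 at 417 to 1022 CPM. Ptprc, which encodes CD45, was present at 2063 to 4810 CPM, while Cd8a, a gene of cytotoxic T cells, stayed between 3.03 and 11.8 CPM. None of the 4 genes Foxp3, Il2ra, Cd4 and Ptprc passed the test in any of the 5 contrasts for which the rule names them. Their lowest values in SPF mice came from tumor-free library 1 (Foxp3 at 485 CPM) and tumor-bearing library 2 (Foxp3 at 760 CPM).

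Markers of other cells differed between the libraries. The other-cell marker score, the mean log2 CPM over the B cell, plasma cell, macrophage, dendritic cell and fibroblast lists, ran from 1.74 to 4.79 in SPF and from 4.79 to 6.12 in GF libraries. Its correlation with housing over the 12 libraries was 0.807, so a fit with the score as a covariate also removes part of any housing difference. Lyz2, a lysozyme gene of macrophages, was present at 17.3 to 1277 CPM in SPF libraries and at 802 to 2678 CPM in GF libraries. Reads assigned to genes made up 18.3% ± 7.66 of the counted reads in SPF tumor-free, 25.2% ± 7.22 in SPF tumor-bearing, 15.7% ± 2.50 in GF tumor-free and 30.2% ± 6.67 in GF tumor-bearing libraries (SD, n = 3 each). A share of 33.9% to 51.6% fell outside annotated features and 28.6% to 38.4% aligned to more than 1 place.

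**Figure D1:**
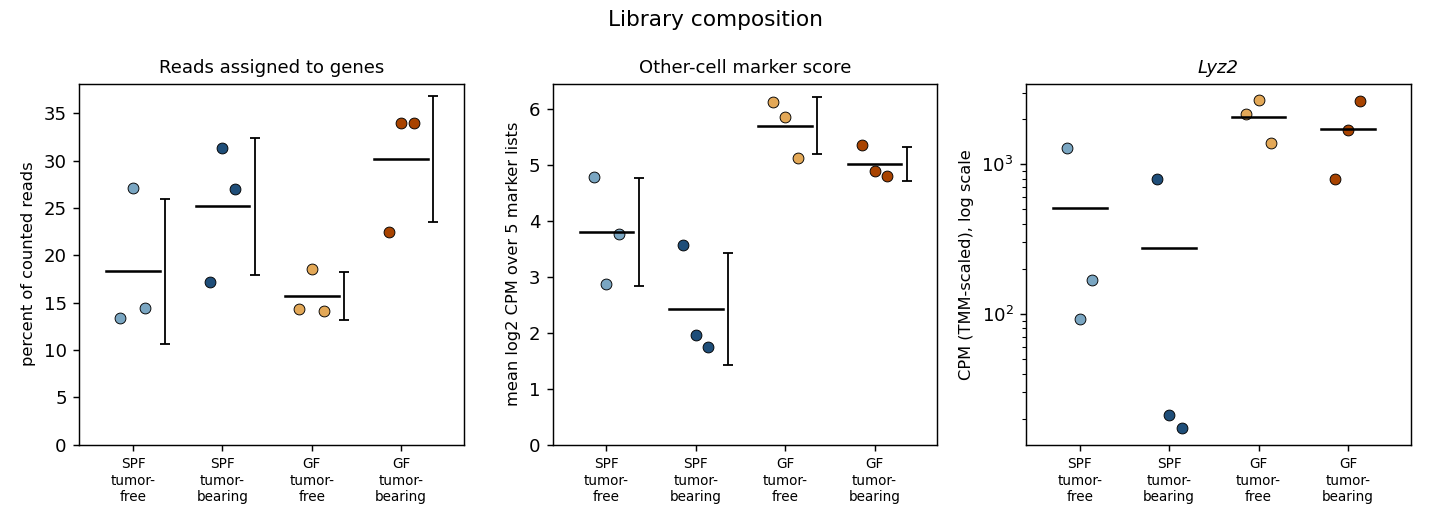
Percent of counted reads assigned to genes, other-cell marker score (mean log2 CPM over 5 marker lists) and Lyz2 (CPM, log axis) in each library; points are libraries, lines are group means and bars are SD (n = 3; no bar for Lyz2). All 6 GF libraries had a score of at least 4.79, and SPF tumor-free library 1 also had a score of 4.79.

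The comparison of GF with SPF mice before tumor injection addressed how the microbiota affects resting omental Tregs. Il10, which encodes a cytokine that restrains inflammation, was lower in GF libraries. It was at 150 ± 22.7 CPM in GF against 449 ± 16.1 CPM in SPF libraries (SD, n = 3 each), a log2 fold change of −1.58 ± 0.24 (adjusted p = 0.0377; chromosome 1, 131019845 to 131024974). Pcsk1, which encodes a protease that processes prohormones, was lower (−3.71 ± 0.53). So were Ccr3, which encodes a receptor for eotaxins (−2.79 ± 0.43), and Adam8, which encodes a membrane metalloprotease (−1.76 ± 0.26). Sema4a, which encodes a semaphorin, was higher in GF libraries (2.47 ± 0.33, from 17.5 ± 1.78 to 96.3 ± 16.3 CPM). Cd79b, which encodes a part of the B cell receptor, was higher (2.01 ± 0.26, from 19.99 ± 3.53 to 81.2 ± 18.8 CPM). The other higher genes were Plek, which encodes pleckstrin (2.05 ± 0.32), and Ckb, which encodes a creatine kinase (2.04 ± 0.32).

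The next 5 genes by p missed the threshold and are given as values. Thy1, the pan-T surface gene, was at −1.53 ± 0.25 (adjusted p = 0.0508), Zeb2 at 1.91 ± 0.31 and Fads1 at 1.91 ± 0.34. Cish, a feedback inhibitor of cytokine signaling, was at −1.39 ± 0.25. Ctla4, a checkpoint receptor through which Tregs suppress, was at −1.45 ± 0.26 (adjusted p = 0.0677). Foxp3 was at −0.59 ± 0.40, Il2ra at −0.85 ± 0.51, Cd4 at −0.52 ± 0.31 and Ptprc at −0.46 ± 0.29, with adjusted p of 0.597 to 0.674.

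Several Treg lists lay lower in tumor-free GF libraries and marker lists of other cells lay higher. Of 22 adipose and tissue Treg genes 1 passed over all genes (Il10) and 14 were lower adjusted over the list alone. Their median was −0.99 (adjusted p = 2.11e-17 with the preset correlation and adjusted p = 0.145 with an estimated correlation). The median was −0.65 for the 15 Treg identity genes, of which 0 passed over all genes and 4 adjusted over the list alone (adjusted p = 0.296 with an estimated correlation). Treg suppressive molecules had a median of −0.62 (adjusted p = 0.296 with an estimated correlation). Of these 18 genes 1 was lower over all genes, and 5 were lower and 1 higher adjusted over the list alone. The 16 pan-T genes lay about as low, with a median of −0.659 (15 negative, 0 passing), so the medians do not set the Treg identity and suppressive lists apart from them. A general fall of T cell RNA and the difference between these lists and the pan-T genes were not tested. The 11 type 17 genes had a median of −0.52, and were called lower with the preset correlation (adjusted p = 0.109 with an estimated correlation). A further 8 lists were called lower with the preset correlation but not with an estimated correlation (adjusted p = 0.296 to 0.680 with an estimated correlation). They were type I interferon genes (−0.53, 0 of 28 passing, with Irf9 at −0.80 and Ifit1 at −1.31), type II interferon genes (−0.61), NF-kB target genes (−0.47) and homing receptors (−0.42). Cholesterol synthesis (−0.43), oxidative phosphorylation (−0.37), type 2 genes (−0.28) and ribosomal proteins (−0.24) were the others. Cell cycle genes had a median of 0.65, with 0 of 34 passing and 6 higher adjusted over the list alone (adjusted p = 0.346 with an estimated correlation). Rrm2, which encodes a subunit of ribonucleotide reductase, was at 1.63 and Bub1b, which encodes a spindle checkpoint kinase, at 1.2. Marker medians moved with this contrast. They were 2.42 for plasma cells (Derl3 at 3.50, Mzb1 at 3.52) and 2.28 for macrophages (Adgre1 at 2.79, Apoe at 3.81). They were 1.73 for B cells, 1.59 for dendritic cells (Itgax at 3.32, H2-Ab1 at 2.66) and 1.24 for fibroblasts. Cd79b was the only passing member of these 5 lists (adjusted p = 0.198 to 0.36 with an estimated correlation).

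By the edgeR quasi-likelihood test with Benjamini-Hochberg adjustment, 9 of 17604 genes passed between tumor-free GF and SPF libraries, 4 higher and 5 lower, and 1849 genes had an unadjusted p under 0.05 where chance gives 880. The 2 groups did not overlap for 13.5% of genes, against 10% by chance. The count was 0 without SPF tumor-free library 2 or 3, any GF tumor-free library or GF tumor-bearing library 2, 2 without SPF tumor-bearing library 3 and 4 without GF tumor-bearing library 3. It was 59 (38 higher, 21 lower) without SPF tumor-free library 1 and 159 (128 and 31) without SPF tumor-bearing library 2. Without both, the libraries with the lowest assigned share of the 2 SPF groups, it was 1019 (645 and 374). These 2 libraries also had the highest other-cell scores of their groups (4.786 and 3.568). Leaving them out thus widened the gap in score between the housings, so the 1019 genes cannot be tied to housing alone. The count was 37 (30 and 7) with only the 2 groups. With the other-cell score as a covariate 88 genes passed (82 higher, 6 lower), of which 2 were among the 9. Il10 was then at −1.4 (adjusted p = 0.054), Pcsk1 at −2.09 (adjusted p = 0.054), Ccr3 at −1.28 (adjusted p = 0.115), Sema4a at 1.61 (adjusted p = 0.0603) and Plek at 1.35 (adjusted p = 0.0897). Foxp3 moved to 0.91 and the Treg identity median to 0.31.

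**Figure D2:**
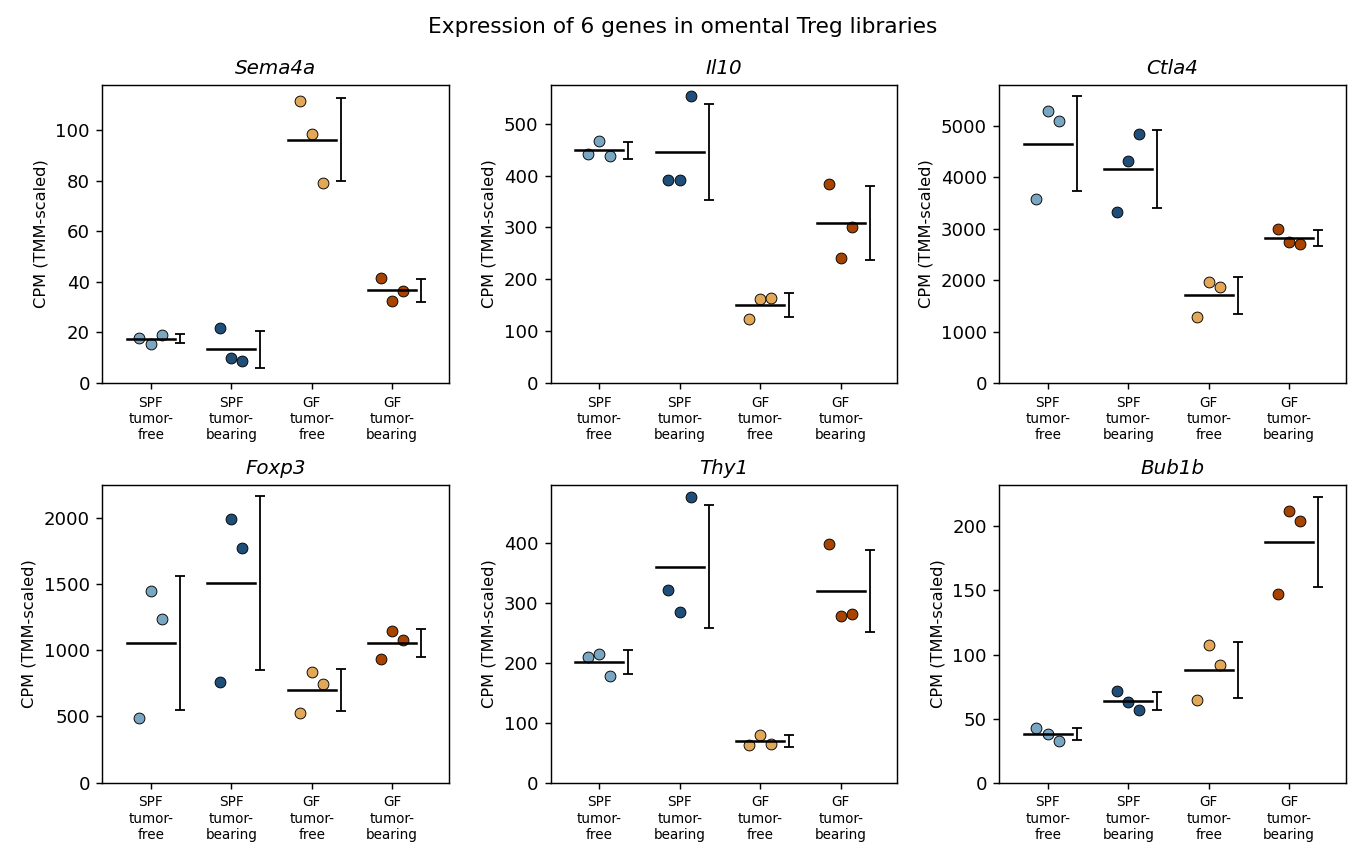
TMM-scaled CPM of Sema4a, Il10, Ctla4, Foxp3, Thy1 and Bub1b in each library of the 4 groups; points are libraries, lines are means and bars are SD (n = 3). Sema4a lay between 32.45 and 111.5 CPM in the 6 GF libraries and between 8.56 and 21.62 CPM in the 6 SPF libraries.

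The same comparison in tumor-bearing mice addressed whether housing affects Tregs of a tumor-bearing omentum. Of the 34 cell cycle genes 6 passed, all higher in GF libraries, and the list as a whole was not called with an estimated correlation. Bub1b was at 188 ± 35.2 CPM in GF against 63.7 ± 7.12 CPM in SPF libraries (SD, n = 3 each), a log2 fold change of 1.56 ± 0.25 (adjusted p = 0.0425; chromosome 2, 118598211 to 118641591). Rrm2 was at 470 ± 95.03 against 161 ± 43.5 CPM (1.54 ± 0.29) and Plk1, which encodes a mitotic kinase, at 110 ± 30.1 against 26.5 ± 4.27 CPM (2.05 ± 0.35). Aspm (2.12 ± 0.32) and Cdca8 (1.81 ± 0.35), which act at the mitotic spindle, were higher as well. So were Trip13 (2.55 ± 0.41), which acts in the spindle checkpoint, and Rfc5 (2.37 ± 0.39), a DNA replication factor. Ppp1r3b, which encodes a glycogen-targeting phosphatase subunit, was lower in GF libraries (−1.41 ± 0.23, from 90.7 ± 12.9 to 34.2 ± 3.00 CPM). The heat shock genes Hspa1a (4.81 ± 0.92) and Hspa1b (4.59 ± 0.92) were higher in GF libraries. The same held for the immediate early genes Jun (2.03 ± 0.38) and Fosb (1.89 ± 0.37) and for Atf3, a stress-induced transcription factor gene (2.22 ± 0.38).

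Other genes higher in tumor-bearing GF libraries are known from cells other than Tregs. Apoe, an apolipoprotein gene of macrophages, rose from 1.09 ± 0.94 to 196 ± 77.1 CPM (7.58 ± 1.2). Ms4a7 was at 4.23 ± 0.70 and Cxcl16 at 3.22 ± 0.52. The collagen genes Col1a1 (4.14 ± 0.73), Col1a2 (4.47 ± 0.73) and Col3a1 (5.84 ± 1.13) and the collagen chaperone gene Serpinh1 (4.61 ± 0.67) were higher. The antibody-secreting cell genes Jchain (8.06 ± 1.42) and Mzb1 (6.68 ± 1.12), Cd79a of B cells (2.68 ± 0.54) and Klrd1 of cytotoxic cells (3.07 ± 0.61) were higher. The CD8 and cytotoxic T cell list that holds Klrd1 was not called, even with the preset correlation. Creld2, an endoplasmic reticulum stress gene, was at 3.19 ± 0.50. Marker medians were 3.03 for plasma cells (2 of 6 passing), 2.62 for macrophages (1 of 15) and 2.14 for fibroblasts (3 of 9). They were 1.4 for dendritic cells (0 of 11) and 1.02 for B cells (1 of 10), and none of the 5 lists was called with an estimated correlation (adjusted p = 0.157 to 0.334 with an estimated correlation).

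Of the 34 cell cycle genes 6 were higher over all genes and 28 adjusted over the list alone. All 34 had positive fold changes, and the median was 1.44 (adjusted p = 6.60e-32 with the preset correlation and adjusted p = 0.157 with an estimated correlation). Of 23 immediate early genes 6 were higher and 12 adjusted over the list alone, with a median of 0.90 (adjusted p = 0.106 with an estimated correlation). Oxidative phosphorylation had a median of 0.24 with 2 of 37 higher, Uqcrfs1 (1.92) and Cyc1 (3.17), both of complex III (adjusted p = 0.577 with an estimated correlation). The mTORC1 list had a median of 0.28 with Cacybp higher at 1.43 (adjusted p = 0.464 with an estimated correlation). Ribosomal proteins had a median of 0.29 with 0 of 80 passing (adjusted p = 0.644 with an estimated correlation). Type I interferon genes had a median of −0.61 with 0 of 28 passing and 6 lower adjusted over the list alone (adjusted p = 0.376 with an estimated correlation). Ifit3 was at −1.47 and Usp18 at −1.06. Type II interferon genes (−0.56), Treg identity (−0.50), type 1 genes (−0.50), Treg suppressive molecules (−0.41), type 17 genes (−0.29) and homing receptors (−0.29) were called lower with the preset correlation. These calls were lost in camera with an estimated correlation (adjusted p = 0.169 to 0.577). Fry called 4 of the 34 lists in this contrast, which are not named here. The 16 pan-T genes had a median of −0.434, close to those of the Treg identity and suppressive lists. Foxp3 was at −0.52 ± 0.40, Il2ra at −0.52 ± 0.51, Cd4 at −0.48 ± 0.31 and Ptprc at −0.36 ± 0.29.

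By edgeR 124 of 17604 genes passed between tumor-bearing GF and SPF libraries, 122 higher and 2 lower, and 2020 had an unadjusted p under 0.05 where chance gives 880. The groups did not overlap for 17.6% of genes, against 10% by chance. Ckb was called higher in both tumor states, where chance gives 0.0277 shared higher genes (Fisher's exact test, two-sided, p = 0.0274). The test rests on 1 shared gene and treats genes as independent, and both contrasts come from 1 model. Across genes, which are not independent replicates, the fold changes of both tumor states had r = 0.41. The count was 0 with the replicate block, with the stricter filter, and without SPF tumor-free library 3, SPF tumor-bearing library 3 or 4, GF tumor-free library 3 or GF tumor-bearing library 2. It was 41 without GF tumor-free library 1, 11 without GF tumor-bearing library 1, 377 without SPF tumor-free library 1 and 338 without SPF tumor-bearing library 2. Over the 10 other settings Bub1b ran from 1.37 to 1.71, Plk1 from 1.85 to 2.21 and Rrm2 from 1.38 to 1.86. With the other-cell score as a covariate 1 gene passed, which was not among the 124, and the cell cycle median was 1.08. Values were then smaller by over 1.5 times for Apoe (3.655), Cxcl16 (1.829), Jchain (3.405), Mzb1 (2.707), Cd79a (0.576), Klrd1 (1.049), Col1a1 (1.87), Col1a2 (1.298), Col3a1 (1.816), Creld2 (2.079), Atf3 (0.993) and Ppp1r3b (−0.871). They were larger by over 1.5 times for Cacybp (2.215) and Fosb (2.865). Foxp3 moved to 1.46, the Treg identity median to 0.86 and the type I interferon median to 0.29, in a fit whose covariate largely follows housing.

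The comparison of tumor-bearing with tumor-free SPF mice addressed how a tumor changes omental Tregs when a microbiota is present. Rhox5, a gene silent in most adult tissues and active in many tumor lines, had at most 4 reads in any tumor-free library. It had 16 to 540 reads in the tumor-bearing libraries. RNA of tumor cells in the sort thus cannot be told apart from a change in Tregs in either tumor contrast. No gene passed, and the genes with the smallest p are given as values. The glycolytic genes Tpi1 (1.79 ± 0.30, from 171 ± 10.8 to 592 ± 172 CPM, adjusted p = 0.189) and Pgam1 (2.26 ± 0.41), the hypoxia-induced gene Bnip3 (1.42 ± 0.24) and Ltf, which encodes lactoferrin (3.63 ± 0.61), had positive values. Anxa1, which encodes the anti-inflammatory protein annexin A1, had a negative value (−1.82 ± 0.29, from 89.2 ± 12.4 to 25.2 ± 6.83 CPM). All 18 glycolysis genes had positive fold changes, with a median of 0.81, 0 passing over all genes and 13 higher adjusted over the list alone (adjusted p = 0.128 with an estimated correlation).

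Cell cycle genes had a median of 0.59 in SPF mice with tumor, with 0 of 34 passing and Rrm2 at 1.61 ± 0.30 (adjusted p = 0.322 with an estimated correlation). Type I interferon genes had a median of 0.51, with 0 of 28 passing and 4 higher adjusted over the list alone (adjusted p = 0.322 with an estimated correlation). Oasl1 was at 1.5 ± 0.36 and Usp18 at 1.2 ± 0.30. Treg suppressive molecules (0.58), type 1 genes (0.40), class I antigen presentation (0.33), mTORC1 target genes (0.30) and Treg identity (0.27) were called higher with the preset correlation. So were oxidative phosphorylation (0.22), ribosomal proteins (0.11) and tissue Treg genes (0.07), while resting T cell genes (−0.50) and immediate early genes (−0.38) were called lower. No member of these 10 lists passed over all genes (adjusted p = 0.322 to 0.699 with an estimated correlation). Marker medians were −1.89 for fibroblasts (Dcn at −3.95 ± 0.89), −1.44 for B cells (Cd79a at −2.55 ± 0.55) and −1.23 for plasma cells (Jchain at −5.83 ± 1.31). They were −0.97 for NK cells, −0.81 for macrophages, −0.73 for conventional CD4 T cells, −0.70 for dendritic cells and −0.44 for neutrophils and mast cells. These 8 marker calls were also lost (adjusted p = 0.322 to 0.456 with an estimated correlation). Foxp3 was at 0.51 ± 0.40, Il2ra at 0.67 ± 0.51, Cd4 at 0.17 ± 0.31 and Ptprc at 0.06 ± 0.29.

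By edgeR 0 of 17604 genes passed between tumor-bearing and tumor-free SPF libraries, with 1254 at an unadjusted p under 0.05 where chance gives 880, while DESeq2 called 39 and limma-voom 3. The groups did not overlap for 7.65% of genes, against 10% by chance, and the median of all genes was −0.11. The count was 231 without SPF tumor-bearing library 2, 1 without SPF tumor-bearing library 4 and 202 without both SPF libraries of lowest assigned share. Treg identity (−0.46), tissue Treg genes (−0.16) and Foxp3 (−0.47) had the opposite sign with the other-cell score as a covariate. The tissue Treg median was −0.18 with the replicate block and −0.19 with the assigned share as a covariate.

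The comparison of tumor-bearing with tumor-free GF mice addressed the effect of a tumor without a microbiota. As in SPF mice, RNA of tumor cells in the sort cannot be told apart from a change in Tregs. Rhox5 had 137 to 540 reads in the GF tumor-bearing and at most 1 in the GF tumor-free libraries. Thy1, which encodes the surface glycoprotein Thy-1 of T cells, rose from 69.6 ± 9.34 to 319 ± 68.7 CPM (SD, n = 3 each). Its log2 fold change was 2.20 ± 0.26 (adjusted p = 0.0126; chromosome 9, 44043384 to 44048579). The next 5 genes missed the threshold, with an adjusted p of 0.0658 each. They were Gpr160 (2.47 ± 0.37), Mmd (2.31 ± 0.36), Pnkd (1.65 ± 0.26), Psat1 of serine synthesis (1.55 ± 0.25) and Bcat1 of branched-chain amino acid breakdown (1.52 ± 0.25). Genes of tissue Tregs had positive values, among them Klrg1, a receptor of differentiated T cells (2.20 ± 0.40, from 142 ± 36.5 to 652 ± 186 CPM). Others were Ccr8, a chemokine receptor of tissue Tregs (1.61 ± 0.33), Il10 (1.04 ± 0.24) and Lgals1 (1.36 ± 0.30).

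The 22 tissue Treg genes had a median of 0.93 in GF mice with tumor, with 0 passing over all genes and 14 higher and 1 lower adjusted over the list alone (adjusted p = 0.307 with an estimated correlation). The 34 cell cycle genes had a median of 1.24, with 0 passing and 33 higher adjusted over the list alone (Rrm2 at 1.53, Tk1 at 1.24; adjusted p = 0.262 with an estimated correlation). Metabolic lists had positive medians with 0 members passing over all genes. Glycolysis had 1.07, with 12 of 18 higher adjusted over the list alone including Tpi1 (1.77) and Pgk1 (1.23) (adjusted p = 0.262 with an estimated correlation). Oxidative phosphorylation had 0.80, with 33 of 37 including Uqcrfs1 (1.98) and Cycs (0.99) (adjusted p = 0.335 with an estimated correlation). For mTORC1 target genes it was 0.76, with 20 of 41 including Phgdh (1.22) (adjusted p = 0.179 with an estimated correlation). Treg suppressive molecules (0.86, 10 of 18 higher adjusted over the list alone), class I antigen presentation (0.63), ribosomal proteins (0.62) and Treg identity (0.59) were called higher with the preset correlation. So were NF-kB target genes (0.56), arginine and polyamine metabolism (0.55), immediate early genes (0.54), type I interferon genes (0.48) and homing receptors (0.37). These 9 calls were lost in camera with an estimated correlation (adjusted p = 0.335 to 0.587). Fry called 9 of the 34 lists in this contrast, which are not named here. Marker medians were −1.59 for B cells (Bank1 at −1.63, Cd79b at −1.0), −1.19 for conventional CD4 T cells (Il21 at −3.43) and −0.98 for neutrophils and mast cells (adjusted p = 0.179 to 0.420 with an estimated correlation). The assigned share was also higher with tumor in GF mice, at 30.2% ± 6.67 against 15.7% ± 2.50 (SD, n = 3 each). Foxp3 was at 0.59 ± 0.40, Il2ra at 0.99 ± 0.51, Cd4 at 0.22 ± 0.31 and Ptprc at 0.17 ± 0.29.

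By edgeR 1 of 17604 genes passed between tumor-bearing and tumor-free GF libraries, 4522 had an unadjusted p under 0.05 where chance gives 880, and 1147 had an adjusted p under 0.1. The groups did not overlap for 40.8% of genes, against 10% by chance, while DESeq2 called 1820 genes and limma-voom 9173. With the assigned share as a covariate 0 genes passed, Foxp3 was at −0.32, and the medians of Treg identity (−0.21) and homing receptors (−0.37) had the opposite sign. The share ran from 14.1% to 18.6% in GF tumor-free and from 22.5% to 34.0% in GF tumor-bearing libraries. The 2 ranges do not overlap, so a fit with the share also removes part of any tumor difference. The call of Thy1 was lost without any 1 of the 3 GF tumor-free libraries or GF tumor-bearing libraries 1 and 2. Its fold change stayed between 2.01 and 2.32 with each library left out and between 2.102 and 2.274 over the 10 other settings. The count was 2 without SPF tumor-bearing library 4, 3 without GF tumor-bearing library 3 and 18 without SPF tumor-free library 1. It was 309 without SPF tumor-bearing library 2, 2142 without both SPF libraries of lowest assigned share and 824 with only the 2 GF groups. No SPF library enters this contrast itself. SPF libraries act on its count through the spread, filter and scaling that all 12 libraries share, so the count of 1 is not a property of the GF libraries alone.

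The interaction asked whether the tumor effect differs between housings. No gene passed, and the genes with the smallest p are given as values in each housing. Serpinh1 had a tumor fold change of 1.60 ± 0.56 in GF and −2.93 ± 0.67 in SPF mice, and Pcsk1 had 2.23 ± 0.51 and −0.47 ± 0.46. Mmd had 2.31 ± 0.36 in GF and 0.34 ± 0.35 in SPF mice, Eif3b 1.82 ± 0.32 and −0.15 ± 0.32, and H2afx 3.20 ± 0.67 and −0.84 ± 0.75. Among Treg genes, Klrg1 had 2.20 ± 0.40 in GF and 0.13 ± 0.39 in SPF mice. Areg, which encodes a growth factor of tissue repair, had 1.82 ± 0.42 and −0.32 ± 0.42, and Il10 had 1.04 ± 0.24 and −0.01 ± 0.24. The interaction values were 0.07 ± 0.56 for Foxp3, 0.32 ± 0.72 for Il2ra, 0.05 ± 0.43 for Cd4 and 0.10 ± 0.40 for Ptprc.

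The tumor fold change was called more positive in GF than in SPF mice with the preset correlation for 9 lists. A positive value can also come from negative fold changes in SPF mice, as for fibroblast markers and immediate early genes. Among the 9 lists were fibroblast markers (median 2.29), immediate early genes (0.77), tissue Treg genes (0.76), cell cycle (0.70) and oxidative phosphorylation (0.56). The others were ribosomal proteins (0.53), mTORC1 target genes (0.49), cholesterol synthesis (0.49) and NF-kB target genes (0.37). None was called in camera with an estimated correlation (adjusted p = 0.323 to 0.651), and fry called 0 lists. By edgeR 0 of 17604 genes passed, with a smallest adjusted p of 0.995 and 657 genes at an unadjusted p under 0.05 where chance gives 880, while DESeq2 called 1 gene and limma-voom 0. The values of Foxp3, Il2ra, Cd4 and Ptprc were negative with the assigned share as a covariate (−0.35, −0.22, −0.38 and −0.23).

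Averaged over both tumor states, the comparison of GF with SPF mice addressed the housing difference with 6 libraries on each side. Il10 (−1.05 ± 0.17, adjusted p = 0.00945) and Ctla4 (−1.01 ± 0.18, adjusted p = 0.0153) were lower in GF libraries. Cish (−1.14 ± 0.17), Ccr2, a chemokine receptor of inflammatory migration (−1.15 ± 0.22), and Klrg1 (−1.24 ± 0.28) were lower. The inhibitory receptor gene Tigit (−0.95 ± 0.18), the costimulatory receptor gene Tnfrsf4 (−0.80 ± 0.18) and the transcription factor gene Maf (−0.96 ± 0.21) were lower as well. Odc1 of polyamine synthesis (−1.05 ± 0.21), the glucose transporter gene Slc2a1 (−0.67 ± 0.17) and the interferon-induced genes Ifit1 and Ifit3 (−1.36 ± 0.31 each) were lower too. Among higher genes were the cell cycle genes Bub1b (1.38 ± 0.18), Rrm2 (1.58 ± 0.21) and Plk1 (1.64 ± 0.24). Sema4a (1.97 ± 0.23), Ckb (1.88 ± 0.22), Fads1 of fatty acid desaturation (1.5 ± 0.23) and Gatm of creatine synthesis (1.46 ± 0.31) were higher. Cacybp (1.0 ± 0.20), Tgfb1, a suppressive cytokine gene (2.09 ± 0.48), and Hspa1a (3.74 ± 0.65) were higher as well. The passing markers of plasma cells, macrophages and B cells were higher, among them Apoe (5.69 ± 0.77), Jchain (5.96 ± 0.90), Mzb1 (5.10 ± 0.71), Cd79a (2.39 ± 0.37) and Adgre1 (2.83 ± 0.50), in lists not called with an estimated correlation. Mmp9 of the neutrophil and mast cell list was lower (−1.27 ± 0.31, adjusted p = 0.0373). Ciita, the regulator of class II genes and a type II interferon gene, was higher (2.20 ± 0.37).

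Of the 22 tissue Treg genes 7 were lower over all genes and 12 adjusted over the list alone, with a median of −0.56 (adjusted p = 0.151 with an estimated correlation). Of 15 Treg identity genes 3 were lower over all genes and 7 adjusted over the list alone (median −0.56, adjusted p = 0.284 with an estimated correlation). Of 18 suppressive molecules 4 were lower and 1 higher over all genes and 7 lower and 2 higher adjusted over the list alone (median −0.44, adjusted p = 0.310 with an estimated correlation). The 16 pan-T genes had a median of −0.523 (quartiles −0.646 and −0.398, 15 negative, 0 passing), so the medians do not set these 3 Treg lists apart from them. Again, neither a general fall of T cell RNA nor the difference from the pan-T genes was tested. Type I interferon genes had 3 of 28 lower over all genes and 15 adjusted over the list alone (median −0.58, adjusted p = 0.274 with an estimated correlation). Type II interferon genes had 2 of 21 lower and 1 higher (median −0.55, adjusted p = 0.347 with an estimated correlation). Homing receptors (−0.49, 2 of 21 lower), type 17 genes (−0.38) and type 1 genes (−0.35, 0 of 15) were called lower with the preset correlation (adjusted p = 0.349, 0.133 and 0.474 with an estimated correlation). Of 34 cell cycle genes 18 were higher over all genes and 26 adjusted over the list alone (median 1.06, adjusted p = 0.138 with an estimated correlation). Of 23 immediate early genes 7 were higher over all genes and 11 adjusted over the list alone (median 0.79, adjusted p = 0.138 with an estimated correlation). Marker lists moved with housing, with 3 of 6 plasma cell genes (median 2.72), 8 of 15 macrophage genes (2.32) and 4 of 9 fibroblast genes (1.9) higher over all genes. The same held for 4 of 11 dendritic cell genes (1.5) and 6 of 10 B cell genes (1.38) (adjusted p = 0.133 to 0.149 with an estimated correlation for the 5 lists). Fry called 9 of the 34 lists in the averaged contrast, which are not named here.

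By edgeR 739 of 17604 genes passed in the averaged comparison, 653 higher and 86 lower, and 3018 had an unadjusted p under 0.05 where chance gives 880. With the other-cell score as a covariate 287 genes passed, of which 18 were among the 739, including Rrm2 (1.85), Odc1 (−1.56) and Cacybp (1.68). Klrg1 (0.34), Maf (0.11) and the medians of Treg identity (0.58), suppressive molecules (0.42), tissue Treg genes (0.16) and homing receptors (0.41) then had the opposite sign. The same held for type I interferon (0.08), type II interferon (0.34) and type 1 genes (0.40). Calls were lost with smaller values for Il10 (−0.84, adjusted p = 0.105), Fads1 (1.12), Ckb (1.52), Hspa1a (3.36), Mmp9 (−0.92), Bub1b (1.3, adjusted p = 0.062), Ctla4 (−0.38, adjusted p = 0.398), Tigit (−0.42), Tnfrsf4 (−0.24), Ccr2 (−0.14), Cish (−0.62), Ifit1 (−0.24), Ifit3 (−0.36), Sema4a (1.02, adjusted p = 0.0924) and Gatm (0.65). The markers Apoe (2.39), Jchain (1.97), Mzb1 (1.54), Cd79a (0.53) and Adgre1 (0.51) and Ciita (0.52) also lost theirs, as did Slc2a1 (−1.11), Plk1 (1.75) and Tgfb1 (2.65) with larger values. With each library left out the call was kept in 3 of 12 fits for Slc2a1, 4 for Tnfrsf4, 5 for Klrg1, Maf, Ifit1, Ifit3 and Mmp9 and 6 for Gatm and Tgfb1. It was kept in 7 for Cacybp, 8 for Ccr2 and Tigit, 9 for Ctla4 and Adgre1 and 10 for Odc1 and Hspa1a. For the other genes named, Il10 among them, it was kept in 12. The count was 1495 without SPF tumor-free library 1 and 84 to 99 without SPF tumor-free libraries 2 or 3 or SPF tumor-bearing library 3. It was 155 and 245 without GF tumor-free libraries 1 and 3, and 133 and 406 without GF tumor-bearing libraries 2 and 3.

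A few lists were not called in any of the 6 contrasts with the preset correlation. Their lowest and highest medians were −0.26 and 0.31 for the integrated stress response, −0.36 and 0.44 for CD8 and cytotoxic T cell markers and −0.95 and 0.79 for mesothelial cells. They were −2.09 and 1.94 for adipocytes, −1.01 and 0.12 for endothelial cells and −0.63 and 0.31 for immature thymocytes. Alas2, the single tested erythroid gene, was at −0.79 in the averaged contrast (adjusted p = 0.526).

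**Figure D3:**
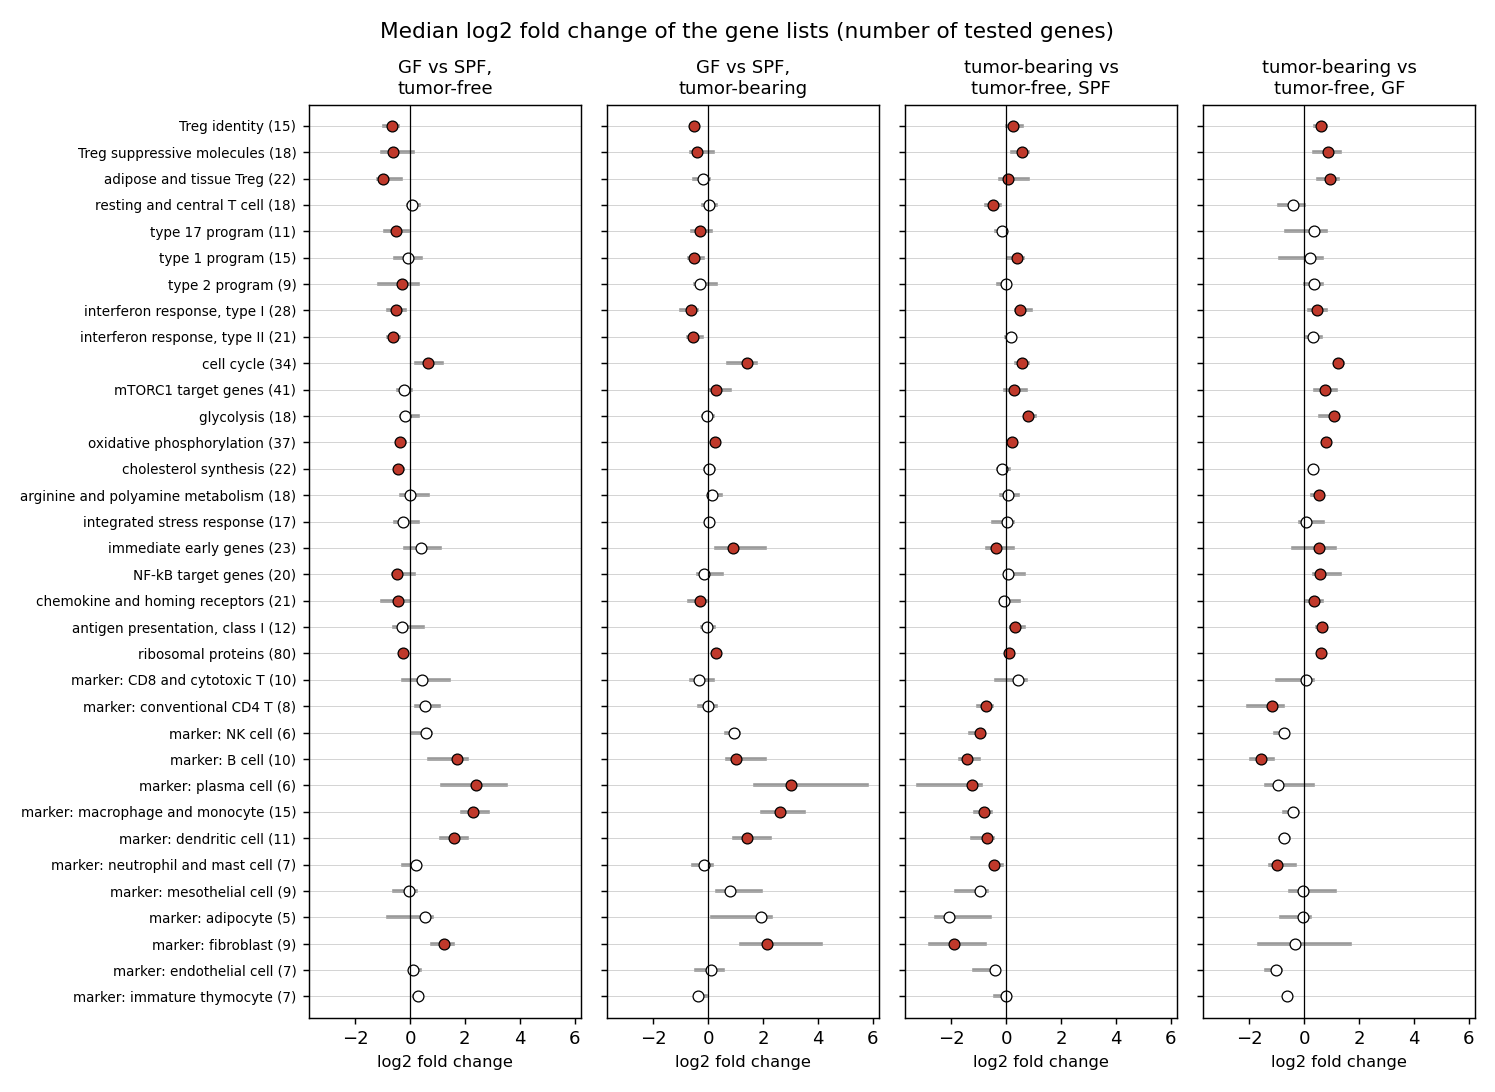
Median log2 fold change of the 34 tested gene lists in 4 contrasts; circles are medians, grey bars span the quartiles of the members, and red marks an adjusted p under 0.05 with the preset correlation of 0.01. With an estimated correlation 0 of the 34 lists were called in any contrast, and the largest positive medians between GF and SPF mice were 2.42 in tumor-free and 3.03 in tumor-bearing mice, both for plasma cell markers.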

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

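The dilution test for Il10, the Rhox5 test of the cell cycle pattern and the covariate fits were chosen only after the results were seen.

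For 9 gene lists the tumor effect differed between GF and SPF mice by the interaction test with the preset correlation. The median interaction was 2.29 for fibroblast markers, 0.77 for immediate early genes, 0.76 for adipose and tissue Treg genes, 0.70 for cell cycle genes and 0.56 for oxidative phosphorylation. It was 0.53 for ribosomal proteins, 0.49 for mTORC1 target genes, 0.49 for cholesterol synthesis and 0.37 for NF-kB target genes. With an estimated correlation 0 of the 9 were called, with adjusted p from 0.323 to 0.651, so a difference between housings is not shown for any of them.

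Markers of B cells, plasma cells, macrophages and fibroblasts were higher in GF libraries, with a median of 2.16 over their 40 members in the averaged contrast, of which 1 (Prdm1) is also in the tissue Treg list. The assigned share does not account for this, since the median was 2.59 with the share as a covariate (2.30 to 2.75 with each library left out). RNA or cells of other types in the sort may account for it. Members varied together within groups beyond the 95th percentile of matched lists in 4 of the 4 lists. Mean correlations were 0.657 (B cells), 0.173 (plasma cells), 0.760 (macrophages) and 0.447 (fibroblasts) against percentiles of 0.120, 0.108, 0.192 and 0.092. The cell cycle list (0.549 against 0.397) and the Treg identity list (0.65 against 0.621) also exceeded theirs. Genes regulated together within a cell type thus pass as well, and the correlations do not decide the source. Genes of the 4 marker lists reached high levels, with Lyz2 up to 2678, Jchain up to 3077, Col3a1 up to 552 and Cd79a up to 167 CPM. The gate on CD45.2, CD4, CD25 and GFP should remove cells of these other types. Whether GF omentum holds more such cells or the sorts differed in purity was not tested and stays open.

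Cell cycle genes had higher values in tumor-bearing GF than SPF libraries, with a median of 1.44 and 6 of 34 genes called, but the list was not called with an estimated correlation (adjusted p = 0.157). With the replicate block or the stricter filter edgeR called 0 genes of any kind in this contrast, although Bub1b stayed between 1.37 and 1.71 and Plk1 between 1.85 and 2.21 over the 10 other settings. With the other-cell score as a covariate the median was 1.08 (0.843 to 1.41 with each library left out), above the 0.719 that is 1/2 of the pattern, but the mean of the list was 1.13 ± 0.561 (SE over libraries) against 1.4 ± 0.3 without it, and the score follows housing (correlation 0.807), so RNA of other cells cannot be told apart from a change in Tregs. With the assigned share as a covariate the median was 1.504 (1.32 to 1.79 with each library left out) and the mean 1.39 ± 0.338, which argues against that share as the whole cause. Tumor cells or their RNA cannot be told apart from division of Tregs either, since Rhox5, a gene with at most 4 reads in any tumor-free library, had a log2 fold change of −0.0107 ± 0.815 with limits from −1.76 to 1.74.

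Il10 was lower in tumor-free GF than SPF libraries (−1.58). Dilution of T cell RNA by that of other cells stays open, since the median of 16 pan-T genes was −0.659, their lower quartile −0.863 and 1/2 of the change of Il10 −0.79. With the assigned share as a covariate Il10 was at −1.60 (−1.72 to −1.50 with each library left out), which argues against that share. With the other-cell score as a covariate, which largely follows housing, it was at −1.404 (adjusted p = 0.054). Without the score its call was lost in 8 of 12 fits without 1 library, with fold changes from −1.706 to −1.495. Over the 10 other settings the call was kept in 9, all but the score. In the averaged contrast the call of Il10 was kept in 12 of 12 fits without 1 library (−1.162 to −0.961). There it was kept in 8 of 9 other settings, but not with the score (−0.84). Since the score largely follows housing, a housing effect on Il10 stays open as well.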

How the results depend on the processing

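The covariate alternatives (assigned share and other-cell score) and the removal of the SPF library with the lowest assigned share in both tumor states were chosen only after the results were seen. The 2 SPF libraries removed also had the highest other-cell scores of their groups (4.786 and 3.568). Their removal widens the gap in score between the housings, so the housing counts without them cannot be tied to housing alone. Settings are compared as counts of genes past the threshold, and the cause was not tested except where stated. The next counts are of combinations of a gene or list with a contrast and a setting, which share libraries and are not independent. Called genes kept direction and call in 995, missed the threshold in 513 and reversed in 2. Genes without a call stayed so in 1417, passed in 189 and reversed in 51. Lists called with the preset correlation kept both in 1403, missed the threshold in 283 and reversed in 38. Replicate numbers are not said to mark a shared animal, day or batch, and the block is therefore only an alternative. Correlations of libraries with the same number, after removing group means, ran from −0.519 to 0.424. In tumor-free GF against SPF 2 of 3 libraries correlated best with their own number, so the correlations do not settle whether the numbers mark pairs. A lone change of scaling to DESeq2 size factors kept the counts within 1.5 times (7, 117 and 594 for the 3 housing contrasts, 0, 1 and 0 for the others). Fry called 1, 4, 1, 9, 0 and 9 lists over the 6 contrasts.

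In tumor-free GF against SPF (9 genes) the count was 21 with the stricter filter, 22 with the replicate block, 26 when thinned, 37 with only the 2 groups, 85 with the share, 88 with the score, 136 with limma-voom, 230 with DESeq2 and 1019 without the 2 SPF libraries. With each library left out it ran from 0 to 159: 0 without SPF tumor-free library 2 or 3, GF tumor-free library 1, 2 or 3 or GF tumor-bearing library 2, 2 without SPF tumor-bearing library 3, 4 without GF tumor-bearing library 3, 59 without SPF tumor-free library 1 and 159 without SPF tumor-bearing library 2. In tumor-bearing GF against SPF (124) it was 0 with the stricter filter and 0 with the replicate block, 1 with the score, 51 when thinned, 65 with only the 2 groups, 273 with no filter, 296 with the share, 648 without the 2 SPF libraries, 706 with DESeq2 and 1766 with limma-voom. With each library left out it ran from 0 to 377: 0 without SPF tumor-free library 3, SPF tumor-bearing library 3 or 4, GF tumor-free library 3 or GF tumor-bearing library 2, 11 without GF tumor-bearing library 1, 41 without GF tumor-free library 1, 338 without SPF tumor-bearing library 2 and 377 without SPF tumor-free library 1.

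For the tumor contrast in SPF mice (0 by edgeR, 1254 at an unadjusted p under 0.05) the count was 3 with the score, 3 with limma-voom, 39 with DESeq2 and 202 without the 2 SPF libraries, with 0 to 231 when each library was left out: 231 without SPF tumor-bearing library 2 and 1 without SPF tumor-bearing library 4. In GF mice (1) it was 0 with the share, 4 with no filter, 4 with the replicate block, 6 when thinned, 34 with the score, 824 with only the 2 groups, 1820 with DESeq2, 2142 without the 2 SPF libraries and 9173 with limma-voom. With each library left out it ran from 0 to 309: 0 without GF tumor-free library 1, 2 or 3 or GF tumor-bearing library 1 or 2, 2 without SPF tumor-bearing library 4, 3 without GF tumor-bearing library 3, 18 without SPF tumor-free library 1 and 309 without SPF tumor-bearing library 2. The interaction (0 by edgeR, 657 at an unadjusted p under 0.05) had 2 with the score and 1 with DESeq2, and from 0 to 0 with each library left out. The averaged contrast (739) had 287 with the score, 1481 with DESeq2, 1832 with the share, 2308 with limma-voom and 2967 without the 2 SPF libraries, and 846 with the replicate block. With each library left out it ran from 84 to 1495: 84 without SPF tumor-bearing library 3, 86 and 99 without SPF tumor-free libraries 3 and 2, 133 and 406 without GF tumor-bearing libraries 2 and 3, 155 and 245 without GF tumor-free libraries 1 and 3, and 1495 without SPF tumor-free library 1. The overlap of the housing calls was 2 genes and 64 with DESeq2, and that of the tumor calls 0 and 13.

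These log2 values reversed with the score as a covariate, which has a correlation of 0.807 with housing and so removes part of any housing difference. In tumor-free GF against SPF they were Foxp3 0.91, Il2ra 1.30, Cd4 0.44, Ptprc 0.32, Treg identity 0.31, suppressive molecules 0.12, type 2 0.098, type I interferon −0.088 (reversed by its test), type II interferon 0.14, oxidative phosphorylation 0.052, homing 0.13 and ribosomal proteins 0.11. In tumor-bearing GF against SPF they were Foxp3 1.46, Il2ra 2.27, Cd4 0.74, Ptprc 0.63, Treg identity 0.86, suppressive molecules 0.75, type 1 0.28, type I interferon 0.29, type II interferon 0.46 and homing 0.64. With tumor in SPF mice they were Foxp3 −0.47, Il2ra −0.71, Cd4 −0.42, Ptprc −0.41, Treg identity −0.46, suppressive molecules −0.094, tissue Treg −0.16, type 1 −0.13, oxidative phosphorylation −0.00015, class I −0.078 and ribosomal proteins −0.11, and in GF mice Cd4 −0.11 and Ptprc −0.096. In the averaged contrast they were Klrg1 0.34, Maf 0.11, Treg identity 0.58, suppressive molecules 0.42, tissue Treg 0.16, type 1 0.40, type I interferon 0.080, type II interferon 0.34 and homing 0.41.

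With the assigned share as a covariate the reversed values were Cd4 −0.17, Ptprc −0.20, Treg identity −0.041, tissue Treg −0.19 and ribosomal proteins −0.13 with tumor in SPF mice. In GF libraries the share did not overlap between the tumor states, so that fit also removes part of any tumor difference there. The reversed values in GF mice were Foxp3 −0.32, Il2ra −0.22, Cd4 −0.55, Ptprc −0.42, Treg identity −0.21, type I interferon −0.063, homing −0.37 and class I 0.068 (reversed by its test). For the interaction they were Foxp3 −0.35, Il2ra −0.22, Cd4 −0.38 and Ptprc −0.23. With the replicate block they were Il2ra 0.16 in tumor-bearing GF against SPF and, with tumor in SPF mice, Ptprc −0.11, Treg identity 0.022 (reversed by its test) and tissue Treg −0.18. Thinning gave Ptprc −0.016 with tumor in GF mice and, for the interaction, Foxp3 −0.046, Cd4 −0.15 and Ptprc −0.043, and Cd4 was −0.018 with the stricter filter and −0.060 with limma-voom. With each library left out, ribosomal proteins ran from −0.48 to 0.042 in tumor-free GF against SPF (positive without SPF tumor-free library 2). With tumor in SPF mice Cd4 ran from −0.079 to 0.54 (negative without SPF tumor-free library 1) and Ptprc from −0.17 to 0.35 (negative without SPF tumor-free library 1 or SPF tumor-bearing library 3), and in GF mice Ptprc ran from −0.0078 to 0.33 (negative without GF tumor-free library 1). For the interaction Foxp3 ran from −0.24 to 0.43, Il2ra from −0.070 to 0.75, Cd4 from −0.31 to 0.31 and Ptprc from −0.18 to 0.35, each negative without SPF tumor-free library 2 or SPF tumor-bearing library 2. Foxp3, Cd4 and Ptprc were also negative without GF tumor-free library 1, Foxp3 and Cd4 without GF tumor-bearing library 2, Foxp3 without SPF tumor-free library 3 and Cd4 without GF tumor-free library 3.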

Other observations

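Rhox5 and its test were chosen only after its reads were seen, and the assigned share and the other-cell score as covariates only after the results were seen.

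Rhox5, a reproductive homeobox gene that is silent in most adult tissues and active in many tumor lines, had 385, 311 and 16 reads in SPF and 137, 540 and 472 reads in GF tumor-bearing libraries. It had 4, 0 and 0 reads in SPF and 1, 0 and 0 in GF tumor-free libraries. In 6 of 6 tumor-bearing libraries its level was above the highest tumor-free library, but the gene was picked for these reads, so this decides nothing about their source. Tumor cells or their RNA in the sort may be the source, which stays open, since Rhox5 was not measured in the injected cells here and the gate on CD4, CD25 and GFP should remove tumor cells.

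Other splits of the libraries were counted for each of the 6 contrasts. A comparison of 3 libraries with 3 has 10 splits, too few for a share under 0.05. In 1 of 10 splits the count was as large as the real one for GF against SPF in tumor-free mice (9 genes, highest other 0), for the same contrast in tumor-bearing mice (124, highest other 0) and for the tumor contrast in GF mice (1, highest other 0). For the tumor contrast in SPF mice the real count was 0, which any split reaches (10 of 10), and the highest other was 3464 genes. That split set SPF tumor-free libraries 1 and 3 and SPF tumor-bearing library 2 against the rest. These are the 3 SPF libraries with the lowest assigned shares (13.4%, 14.4% and 17.2%) and with the highest other-cell scores (4.786, 3.758 and 3.568), which points to a structure of the samples that follows both. The real count was 0 with the share and 3 with the score as a covariate.

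For the interaction the real count was 0, which any split reaches (100 of 100 drawn), so the splits decide nothing, and the highest other was 2824 genes. That split put the 3 tumor-free libraries with the lowest shares together with SPF tumor-bearing libraries 3 and 4 and GF tumor-bearing library 3. For the averaged contrast of GF and SPF 2 of 100 drawn splits gave at least 739 genes, the real one included, a share under 0.05. The other, with 1407 genes, set SPF tumor-free library 1, GF tumor-free libraries 1 and 3, SPF tumor-bearing libraries 2 and 4 and GF tumor-bearing library 1 against the rest, which are the 3 libraries with the lowest assigned shares in each tumor state. With the share as a covariate the real contrast gave 1832 genes, of which 737 were among the 739. With the other-cell score, which largely follows housing, the real contrast gave 287, of which 18 were among the 739. A count as large as the real one was thus rare among the splits. The split that follows the share gave more, so the splits alone do not tie the count to housing.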
